A study of Drosophila melanogaster with 2 samples.

How the data were processed

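Peaks of an anti-GFP ChIP-seq experiment were analysed from whole embryos of 0 to 24 h that carried an esg-eGFP transgene. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels' protocols. The labels name 2 biological replicates of 1 group, so p-values across peaks describe these libraries and do not measure the spread between conditions. Read depth is unknown, and intervals cover counting error only.

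The aligner, the peak caller and their versions are not given in the sources used here. Per the text descriptions deposited with the files, peaks are in dm6 coordinates and were made from replicate alignments and a control alignment, with a selection by irreproducible discovery rate (IDR). Each peak has a signal value that the authors deposited, whose unit is not stated. It was used only to rank, describe and filter peaks within a list and to correlate paired peaks. Each peak also has a score on the deposited lists, of which the lowest in a thresholded list was 830. The ranked lists deposited by the authors hold the −log10 of the global IDR. Tested on the files, every thresholded peak was in its ranked list with a −log10 value of at least 2, an IDR of 0.01. From 72 to 125 ranked peaks per list passed that limit and were left out of the thresholded list. The ranked list of the whole series that holds the main list's peaks has 8 further columns of per-replicate values, which were not used. The deposited list that is named conservative served as the main list (4419 peaks). The other list of the whole series had 3761 peaks, and replicates 1 and 2 had 3138 and 3357.

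Peaks on the 7 arms 2L, 2R, 3L, 3R, 4, X and Y were analysed. Annotation was Ensembl release 115 (BDGP 6.54), whose arms have the lengths of dm6, and sequence was the RefSeq assembly of the same genome release. Transposable element entries were left out of the gene annotation. The base at the summit was classified in the order coding exon, 5' UTR, 3' UTR, other exon, intron, intergenic. A peak was assigned to the protein-coding gene with the nearest start site. Positions are 1-based.

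Replicate overlap needed at least 1 bp and gave equal counts with bedtools 2.31.1. Random placements (1000 for overlap, promoter share and annotation classes, and 10000 for gene lists) kept the chromosome, avoided unknown bases and stayed 1500 bp from chromosome ends. Motif windows spanned 100 bp either side of the summit. Control windows lay 1000 bp towards lower coordinates and were compared by an exact McNemar test. GC-matched controls were paired in steps of 2 percentage points, and random ones were drawn from 40 positions per peak on the same arm. Summit windows without a match were left out of such a comparison. Interval bounds on shares are exact Clopper-Pearson at 95%, and the correlation interval used 1000 bootstrap draws. Odds ratios had 0.5 added to each cell. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

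The statistics were tested on simulated data. With 2000 peaks a planted promoter share of 39.1% was measured as 39.0%, a planted 6-mer ranked at position 1, and 0 6-mers were called with nothing planted. A planted overlap of 51.65% was measured as 52.05%. Of 1000 random lists of 15 genes, 2.2% passed an unadjusted p of 0.05. The bound genes of that simulation were drawn at random, so it does not cover lists of genes with large loci. The 6-mer simulation used random positions, so it does not cover summits of lower GC content than their flanks.

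The groups, gene lists, rule for named genes, most tests and most alternatives were fixed before the data were examined. That plan did not hold the division of replicate overlap or promoter share by signal value. Nor did it hold the correlation of signal rank with promoter position or the side of the start site. Genes named were all members of the list fixed for the Snail and Scratch family, those nearest to the 10 strongest peaks, and of each other list up to 3 members nearest to the strongest peaks and the first in alphabetical order with no peak. Members of the ribosomal protein and chemoreceptor families are given as counts. Of 202 members of the other lists, 4 were matched through older symbols. Alternatives were the other series list, each replicate alone, the upper part of each list by signal value, other windows, distances, controls and gene assignments. Random GC-matched windows, the removal of peaks of signal under 20, and the count of named genes with a peak in other lists were chosen after seeing the data.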

Results

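Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole embryos of Drosophila melanogaster collected from 0 to 24 h of development. The embryos carried a transgene of escargot (esg) fused to enhanced green fluorescent protein, and chromatin was precipitated with an antibody against the fluorescent tag. Escargot is a zinc finger transcription factor of the Snail family. The series holds 1 group of 2 biological replicates, with no second condition, so the comparisons are those between the replicates and those between the peaks and the rest of the genome. The main peak list held 4419 peaks that passed a reproducibility threshold between the replicates, of which 4397 lay on the 7 chromosome arms and were analysed. Replicate 1 alone had 3138 peaks and replicate 2 alone had 3357, of which 3105 and 3351 lay on the arms. The sequencing depth behind the peaks is unknown, so intervals on shares of peaks cover counting error only.

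The first question was whether both embryo collections gave the same binding sites. Of the 3105 replicate 1 peaks, 2531 overlapped a replicate 2 peak by at least 1 bp, a share of 81.5% (95% exact binomial interval 80.1 to 82.9). In the opposite direction 2484 of 3351 peaks overlapped, a share of 74.1% (72.6 to 75.6). Random placement of the peaks on the same chromosomes gave mean shares of 1.43% and 1.30%, and no placement reached the observed share (one-sided permutation test, p = 0.0010 both ways, the smallest that 1000 placements can give). Each list was ranked by signal value and divided into 5 equal parts. In the strongest part, 621 of 621 replicate 1 peaks and 669 of 670 replicate 2 peaks were shared. In the weakest part the shares were 49.8% (45.8 to 53.8) and 34.6% (31.0 to 38.3). Against the other replicate's longer ranked list, before the threshold, 98.5% of replicate 1 peaks and 97.9% of replicate 2 peaks overlapped. Random placements gave 14.4% and 23.5% there. Across 2422 pairs of peaks whose summits lay within 100 bp, the signal values had a Spearman rho of 0.876 (95% bootstrap interval 0.863 to 0.887) and a Pearson r of 0.921 on the log2 scale. These correlations are across peaks, which are not independent replicates.

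**Figure D1:**
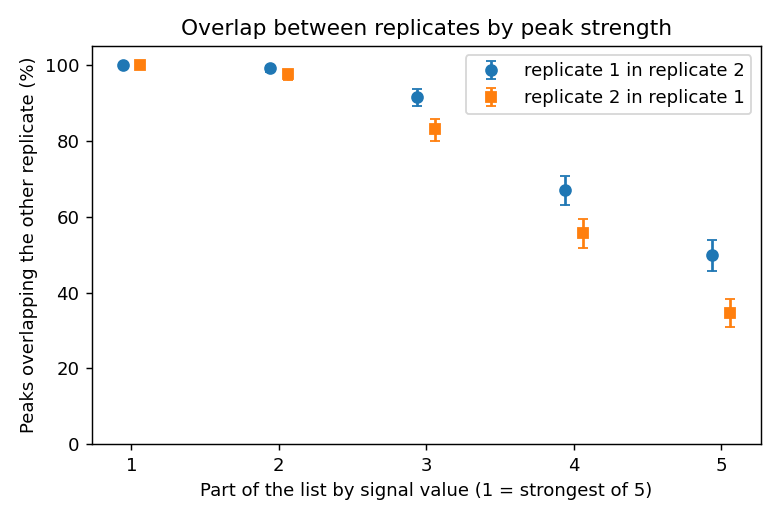
Share of each replicate's peaks (vertical axis, percent) that overlap a peak of the other replicate, in 5 equal parts of the list ranked by signal value (horizontal axis, 1 is the strongest part). Points are shares and bars are 95% exact binomial intervals, and the shares fall from 100% and 99.9% in the strongest part to 49.8% and 34.6% in the weakest.

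Peaks on the thresholded lists of both replicates lay at promoters more often than peaks on a single replicate's list. Most peaks of a single list were not absent from the other library but missed its threshold. Of all replicate 1 and replicate 2 peaks, 98.5% and 97.9% overlapped a peak of the other's ranked list. Of the shared peaks, 46.7% (44.7 to 48.7) had their summit within 500 bp of a transcription start site. The share was 35.2% (31.3 to 39.3) for the 574 peaks of replicate 1 only and 34.3% (31.1 to 37.5) for the 867 peaks of replicate 2 only. Both differences from the shared peaks passed Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 6 tests (adjusted p = 1.46e-06 and 9.14e-10). The promoter shares of the single-replicate sets differed by 0.936 percentage points, which did not pass the exact test (adjusted p = 0.853). The median signal value was 85.1 for shared peaks and 50.3 for peaks of replicate 1 only. These tests compare 2 libraries and not conditions.

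The next comparison asked where in the genome the peaks lay. In the main list, 1863 of 4397 summits (42.4%, 40.9 to 43.8) were within 500 bp of an annotated transcription start site. Random placement on the same chromosomes gave 13.6%, so the observed share was 3.13 times the expected one (two-sided permutation test, p = 0.0020, the smallest that 1000 placements can give). By the annotation at the summit base, 2264 summits (51.5%) were in introns, 38.3% (36.9 to 39.8) were intergenic and 5.21% (4.57 to 5.91) were in 5' UTRs. Coding exons held 31 summits, or 0.705% (0.480 to 0.999), against 17.0% expected. The 3' UTRs held 1.61% against 4.96% expected. Each of the 6 annotation classes differed from the placements (permutation test, adjusted p = 0.0020). Of the 1863 promoter summits, 1546 (83.0%, 81.2 to 84.7) lay upstream of the nearest start site, with a median position of -130 bp. The strongest of 5 equal parts of the list by signal value had a promoter share of 60.4% (57.1 to 63.7) and the weakest part 34.9% (31.7 to 38.1). Signal rank and promoter position were correlated across peaks (Spearman rho 0.165, permutation p = 1e-05, the smallest that 100000 resamples can give).

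**Figure D2:**
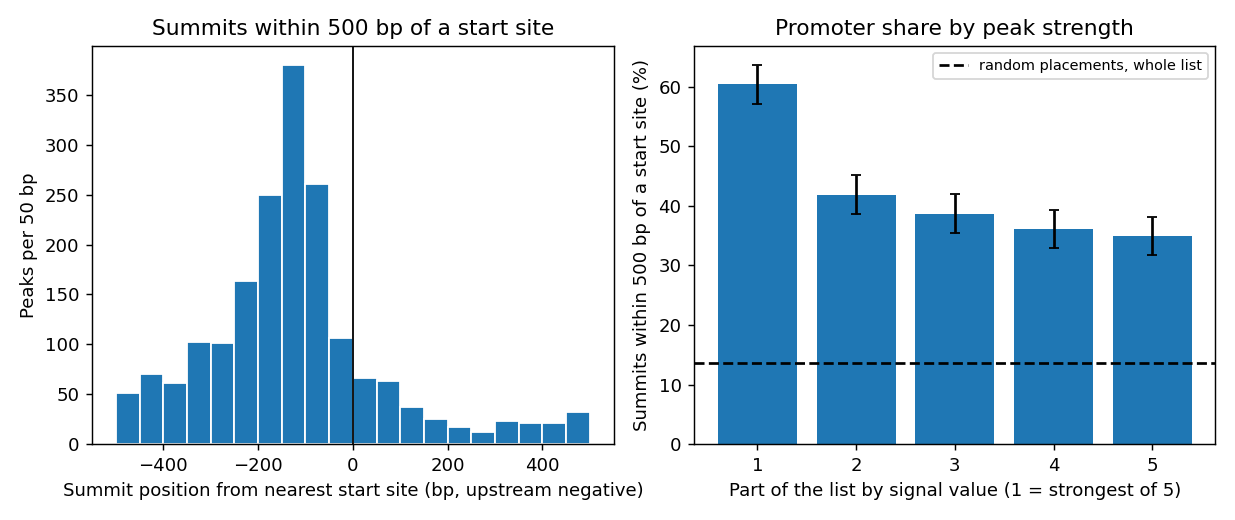
Left, number of summits per 50 bp (vertical axis) by position from the nearest transcription start site (horizontal axis, bp, upstream negative), which is highest at 380 summits from -150 to -100 bp. Right, share of summits within 500 bp of a start site (percent, bars with 95% exact intervals) in 5 equal parts of the list by signal value, falling from 60.4% to 34.9%, with the 13.6% of random placements as a dashed line.

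The 10 strongest peaks were found in both replicates. The peak with the highest signal value, 2451.6, spanned positions 2703713 to 2704043 of the X chromosome (dm6), in intergenic sequence 38 bp from a start site of Ugalt, which encodes a UDP-galactose transporter. The 41 bp around its summit, X 2703870 to 2703910, read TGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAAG and had a GC content of 29.3%. The peak at rank 2 (signal 2249.3, 3L 19590455 to 19590776) was intergenic and 90 bp from CG14100. The peak at rank 3 (signal 2128.4, 2R 15217583 to 15217909) was intergenic and 138 bp from mRpL41, which encodes a mitochondrial ribosomal protein. The peaks nearest to CG7601, CG11050 and Tcs5 had signal values of 1852.9, 1850.2 and 1670.8. PNPase, which encodes a polynucleotide phosphorylase, had an intronic peak of 1620.5 at 78 bp from its start site. The Polycomb group gene ph-p had an intronic peak of 1581.1 at 489 bp, and the HMG-box gene HmgZ an intronic peak of 1509.9 at 588 bp. The peak of 1569.8 nearest to CG13323 was 11914 bp from its start site. None of these 10 peaks had CAGGTG within 100 bp of the summit, and none had ACAGTG, the 6-mer described below. Over all summits of the main list the shares were 5.28% and 20.2%, so 10 peaks are too few to read either absence.

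The list fixed for the Snail and Scratch family was represented by peaks at esg and Kah. Of its 5 members, 2 were nearest to a peak (95% interval of the share 5.27% to 85.3%), against 20.2% of the other protein-coding genes (Fisher's exact test, adjusted p = 0.357). The esg gene (FBgn0287768, 2L 15333866 to 15336138) had 4 peaks, all intergenic and 3590 to 11868 bp from its start site. The strongest (2L 15337288 to 15337623, signal 130.6) ranked at position 1721 and was present in both replicates. The other esg peaks had signal values of 70.8, 58.1 and 19.4, and none of these overlapped a thresholded peak of a single replicate. The peaks of 70.8 and 19.4 overlapped each other, so they are not separate regions. Kah had 1 intergenic peak (3L 589371 to 589539, signal 253.8) at 172 bp from its start site, present in both replicates. No summit of the main list was nearest to sna, wor or scrt, the other genes listed for the family.

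**Figure D3:**
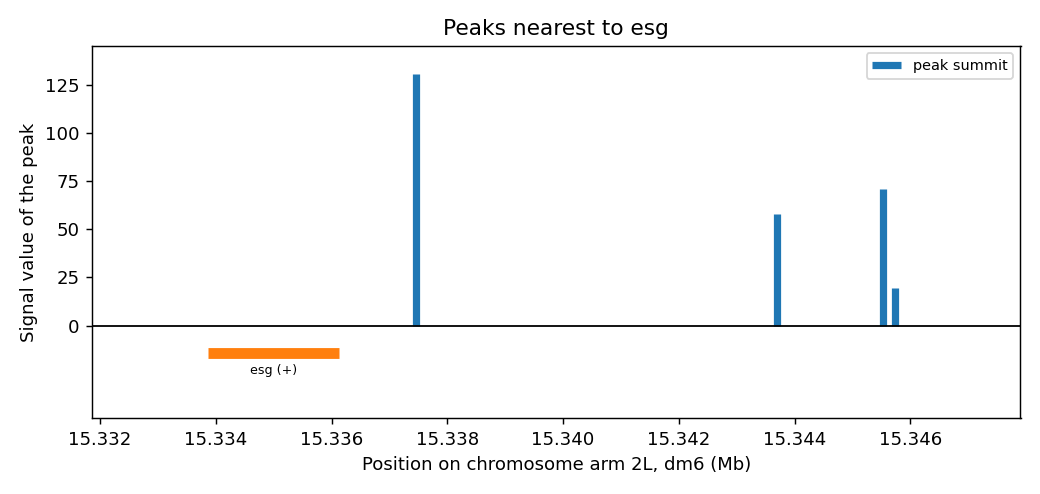
Map of the esg gene (orange bar, plus strand) on chromosome arm 2L (horizontal axis, dm6 position in Mb), with the summits of the 4 peaks nearest to esg as vertical lines whose height is the signal value (vertical axis). The highest line, at 130.6, lies 3590 bp from the start site, and the other 3 lie further downstream.

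Genes of several developmental groups were nearest to a peak more often than other genes. Of 13968 protein-coding genes, 2828 (20.2%) were nearest to at least 1 summit, and 20 gene lists fixed beforehand were tested with Fisher's exact test and Benjamini-Hochberg adjustment. Mesoderm genes had peaks at 9 of 13 members (69.2%, 38.6 to 90.9, odds ratio 8.34, exact test, adjusted p = 0.00182). Among them, the heart homeobox gene tin had a peak of signal 370.5 (rank 343) 219 bp from its start site. The T-box gene Doc2 had 3 peaks, the strongest at 326.0, and the forkhead gene bin had 1 at 216.3, while bap had none. Tracheal genes had peaks at 8 of 12 members (66.7%, 34.9 to 90.1, odds ratio 7.46, exact test, adjusted p = 0.00420). The POU-domain gene vvl had 7 peaks, the strongest at 243.9 and 26263 bp away, rib had 2 peaks and trh had 1, while btl, which encodes a fibroblast growth factor receptor, had none. Pair-rule genes had peaks at 6 of 9 members (odds ratio 7.33, exact test, adjusted p = 0.0163), with slp2 at a signal of 407.7, odd at 149.4 and opa at 104.3, and none at eve. Hox genes had peaks at 5 of 8 members (odds ratio 6.20, adjusted p = 0.0365 by the exact test), including 6 at Antp, 4 at Abd-B and 2 at Ubx, and none at lab.

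The enrichment of those 4 lists was not found against random placements, which hit genes with large loci more often. The placements put 13.6% of summits within 500 bp of a start site, against 42.4% of the observed summits. For these lists and those below, they therefore do not isolate locus size. Against 10000 random placements of the same peaks, mesoderm genes had 1.79 times the expected number of bound members (permutation test, adjusted p = 0.219), pair-rule genes 1.36 times (adjusted p = 0.938), tracheal genes 1.06 times (adjusted p = 1) and Hox genes 0.876 times (adjusted p = 1). With assignment by a summit within 1000 bp of a start site, the odds ratios of the pair-rule and Hox lists fell below 1, to 0.223 and 0.849, and those of the mesoderm and tracheal lists fell to 1.42 and 1.57 (Fisher's exact test, adjusted p = 1 for both). The pair-rule call was also lost without replicate 1 (odds ratio 4.07, exact test, adjusted p = 0.0889), in the upper part of the list by signal (odds ratio 2.40, exact test, adjusted p = 0.503) and by gene body (odds ratio 0.178, exact test, adjusted p = 0.413). The Hox call was lost without replicate 2 (odds ratio 5.41, exact test, adjusted p = 0.0798), in the upper part (odds ratio 4.59, exact test, adjusted p = 0.159) and by gene body (odds ratio 2.15, exact test, adjusted p = 0.606). The tracheal call was lost in the upper part (odds ratio 3.82, exact test, adjusted p = 0.159) and by gene body (odds ratio 3.39, exact test, adjusted p = 0.103). The mesoderm call passed without replicate 1 (odds ratio 10.5, exact test, adjusted p = 0.000386), without replicate 2 (odds ratio 11.4, exact test, adjusted p = 0.000214), in the upper part (odds ratio 15.3, exact test, adjusted p = 5.24e-05) and by gene body (odds ratio 7.16, exact test, adjusted p = 0.00318). Only the ribosomal protein and chemoreceptor genes passed both tests. Cytoplasmic ribosomal protein genes had peaks at 30 of 92 members (32.6%, 23.2 to 43.2, odds ratio 1.93, exact test, adjusted p = 0.0229), which was 2.43 times the placement value (adjusted p = 0.0020). The ribosomal protein call was lost in each replicate's own list (odds ratios of 1.23 and 1.34, exact test, adjusted p = 0.537 and 0.390), in the other list of the whole series (odds ratio 1.59, exact test, adjusted p = 0.121) and in the upper part of the main list by signal (odds ratio 0.916, exact test, adjusted p = 0.970). With assignment by a summit within 1000 bp of a start site it was stronger (odds ratio 3.31, exact test, adjusted p = 6.72e-07). By gene body it also passed (odds ratio 2.63, exact test, adjusted p = 0.000142). Odorant and gustatory receptor genes had peaks at 6 of 119 members (5.04%, 1.87 to 10.7, odds ratio 0.224, exact test, adjusted p = 9.90e-05), 0.252 times the placement value (adjusted p = 0.0020).

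The other lists did not pass the test in the main list. Among neuroblast genes 5 of 13 had peaks, including brat (signal 552.0), numb (469.0) and SoxN (249.9) but not ase. Of the temporal transcription factor genes 1 of 7 had a peak (grh, 223.1), and of the proneural genes 1 of 9 (da, 88.2). Among neuronal genes 3 of 12 had peaks, with elav, which encodes an RNA-binding protein of neurons, at 629.6. Of the muscle structural genes 3 of 10 had peaks, with sls at 275.4, and of the dorsoventral ectoderm genes 4 of 9, with ths, sog and brk at 282.9, 225.6 and 223.3. Of the Notch pathway genes 6 of 15 had peaks, with neur at 362.8 and E(spl)m3-HLH at 315.8. Imaginal disc genes had peaks at 6 of 12 members, with ptc, dpp and hth at 268.0, 267.8 and 266.7. Genes of gut stem cells had peaks at 6 of 13 members, with spi at 586.0 and Stat92E at 250.3. Of the germline and gonad genes 4 of 9 had peaks, and chinmo alone had 8, the strongest at 890.1. Cell cycle genes had peaks at 5 of 16 members, with CycB at 682.0 and Dp at 402.9. Adhesion and polarity genes had peaks at 7 of 17 members, with baz at 229.3, Fas3 at 223.8 and 7 peaks at dlg1. That list passed in the other list of the whole series, in each replicate's own list and by gene body (Fisher's exact test, adjusted p = 0.0481, 0.0432, 0.0412 and 0.0329), and its ratio to random placements was 0.876 (permutation test, adjusted p = 1). The neuroblast and imaginal disc lists passed in the other list of the whole series (Fisher's exact test, adjusted p = 0.0463 and 0.0341), and the dorsoventral ectoderm and gut stem cell lists in the list of replicate 2 alone (adjusted p = 0.0367 and 0.0432 by the exact test). None of 13 eggshell and yolk genes had a peak, with an upper 95% limit of 24.7%.

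**Figure D4:**
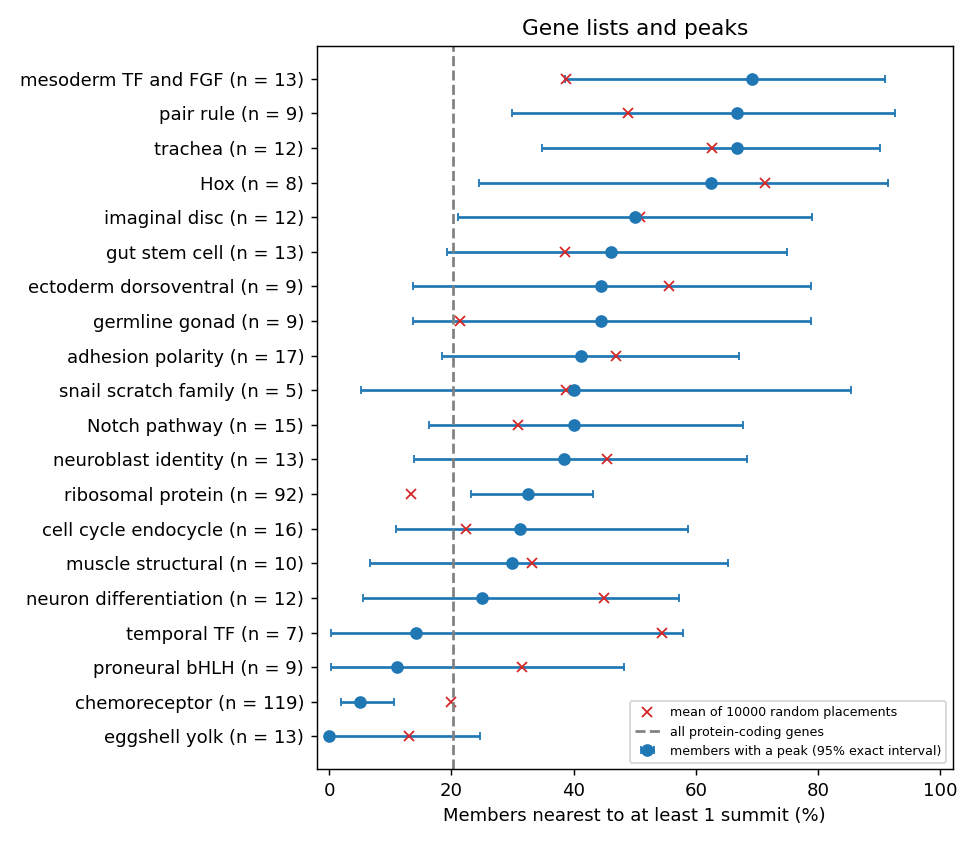
Share of the members of each of the 20 gene lists that are nearest to at least 1 summit (horizontal axis, percent, points with 95% exact binomial intervals, n members beside each name). Crosses are the means of 10000 random placements and the dashed line is the 20.2% of all protein-coding genes. Of the lists that lie away from their crosses, only the ribosomal protein (32.6%) and chemoreceptor (5.04%) lists passed the adjusted permutation test.

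The E-box CAGGTG, the hexamer that Snail-family proteins are known to recognise, was less frequent at summits than beside them. It was present within 100 bp of 232 of 4397 summits (5.28%, 4.63 to 5.98) and in 8.67% (7.85 to 9.54) of the windows of the same size 1000 bp away, a difference of -3.39 percentage points (exact McNemar test, adjusted p = 5.06e-09 over 10 E-boxes). The summit windows had a mean GC content of 34.2%, against 42.3% in the windows 1000 bp away. The direction turned when the control windows had the same GC content. Against peak flanks matched on GC the difference was 0.635 points (exact McNemar test, p = 0.245). That comparison left out summit windows without a match, had a summit share of 5.77%, and did not pair a summit with its own flank. Against random windows matched on GC, a control chosen after the data were seen, the difference was 0.978 points. It did not pass after adjustment over the 10 E-boxes (exact McNemar test, p = 0.0340, adjusted p = 0.0850). Among peaks over 500 bp from a start site the difference from the flank was -1.34 points and did not pass (exact McNemar test, p = 0.0525). Of the other E-boxes, CAACTG, CACATG, CACGTG, CAGATG and CAGCTG were also less frequent at summits than 1000 bp away (adjusted p from 0.000530 to 1.98e-08), and CAAATG, CAAGTG, CAATTG and CATATG did not pass. These comparisons too depended on the control. Against random windows matched on GC, CAGCTG turned to 1.30 points more frequent at summits (exact McNemar test, adjusted p = 0.0422) and CAAGTG was 1.93 points more frequent (adjusted p = 0.0358 by the exact test), and the other E-boxes did not pass. CAGGTG was present in 4.66% (3.37 to 6.27) of the strongest of 5 parts and 6.59% (5.04 to 8.44) of the weakest, and its presence was not correlated with signal rank beyond the threshold (Spearman rho -0.03, permutation p = 0.0603). It passed with the other list of the whole series (rho -0.04, permutation p = 0.00999) and with windows of 50 bp (rho -0.05, permutation p = 0.00257). It was closer to 0 and did not pass without replicate 1 (rho -0.00388, permutation p = 0.823), without replicate 2 (rho -0.0120, permutation p = 0.502), in the upper part by signal (rho -0.000953, permutation p = 0.964) and without peaks of signal under 20 (rho -0.0134, permutation p = 0.382).

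All 2080 canonical 6-mers were then compared between summits and windows 1000 bp away. AT-only 6-mers led the ranking, and the first 20 that were more frequent at summits held no G or C. TTAAAA was present at 53.4% of summits and in 27.1% of flanks. In all, 494 6-mers were more frequent at summits and 1066 less frequent (exact McNemar test, Benjamini-Hochberg adjusted p below 0.05). GC content fell to 30.7% within 20 bp of the summit. Against random windows matched on GC, 239 6-mers were more frequent and 218 less frequent, and the order of the ranking changed. ACAGTG then ranked first, at 20.2% of summits against 7.005% of control windows, a ratio of 2.88 (exact McNemar test, adjusted p = 2.26e-71). CAGTGC, ACACTG and CACTGA followed, with ratios of 2.95, 2.501 and 2.38, and CAGGTG ranked at position 652 with a ratio of 1.23 (exact McNemar test, adjusted p = 0.108). The ratio of ACAGTG depended on the window. Against flanks 1000 bp away it was 2.53 with 100 bp either side of the summit and 1.41 with 50 bp (exact McNemar test, adjusted p = 2.25e-60 and 0.000221).

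**Figure D5:**
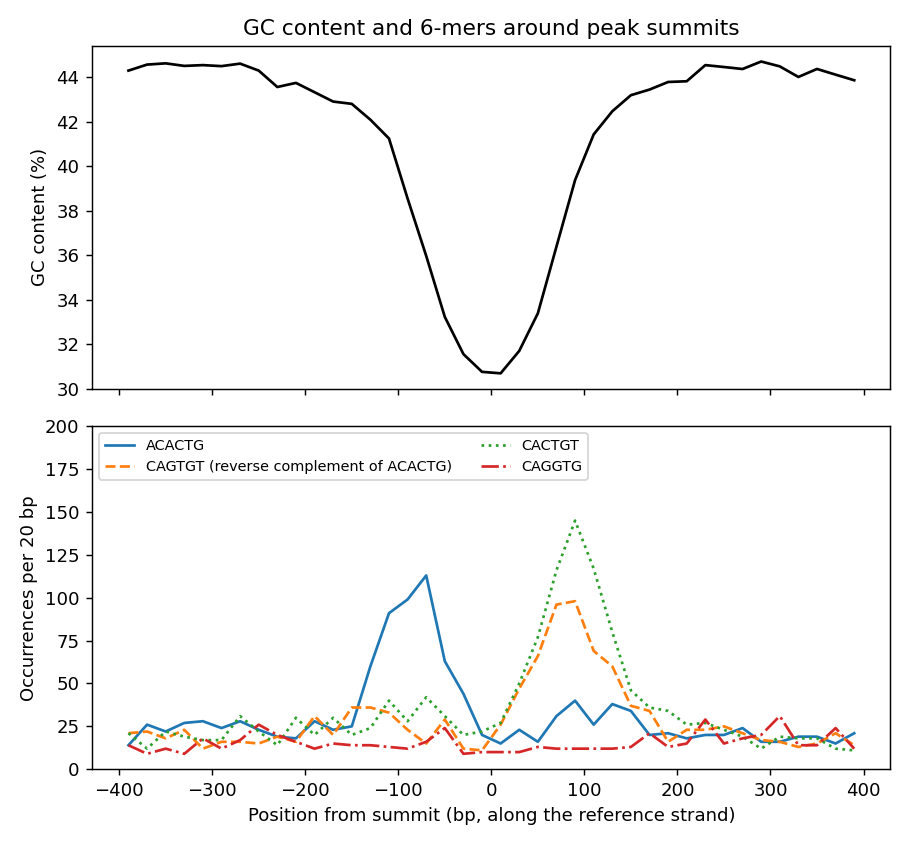
Mean GC content (top, percent) and number of occurrences of 6-mers per 20 bp (bottom) by position from the summit (horizontal axis, bp along the reference strand), over the peaks of the main list. GC content is lowest at the summit, ACACTG is most frequent to the left of it and its reverse complement to the right, and CAGGTG has no such maximum.

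Peaks were spread over the major chromosome arms with the highest density on the X. The X chromosome held 37.8 peaks per Mb (95% exact Poisson interval 35.4 to 40.4), 1.19 times the density of the autosomes (exact binomial test, two-sided, p = 4.23e-06). Arms 2L and 3L had 35.0 (32.7 to 37.5) and 34.3 (32.1 to 36.5) peaks per Mb, and 2R and 3R had 29.1 (27.0 to 31.3) and 30.5 (28.6 to 32.5). The intervals of arms 2L and 3L overlapped that of the X. Densities used full arm lengths, and chromosome 4 was counted with the autosomes. Long stretches without peaks were not taken into account, and they would lower the density of an arm. Chromosome 4 held 2 peaks, or 1.48 per Mb (0.180 to 5.36), and the Y chromosome 3, or 0.818 per Mb (0.169 to 2.39).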

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

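The report's comparisons leave out 22 peaks of the main list (0.498%) that lie on 18 unplaced scaffolds of the X chromosome. They drew attention because they lie in sequence outside the arms analysed. No expected number was computed for the scaffolds, so an excess of peaks there was not tested. Their median signal value was 89.2 (9.94 to 741.1), against 108.1 over the main list. Replicate 1 had 33 peaks on scaffolds and replicate 2 had 6.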

How the results depend on the processing

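Random GC-matched windows, the removal of peaks of signal under 20 and the named gene counts were chosen after seeing the data. Of 255 recomputed values, 196 kept their direction and side of the threshold, or stayed within 1.5 times a count or inside the main interval. Of those 196, 116 were values of single gene lists and 73 were values of main results. In the main list only 5 of the 20 gene lists were enriched and 1 depleted, so many of the 116 merely stayed on the non-passing side. Promoter share (31.2% to 53.4%), replicate overlap and the X ratio kept their direction and side of the threshold in every alternative run. The E-box difference turned to 0.635 points against GC-matched flanks and to 0.978 against random GC-matched windows, and was -1.34 points (exact test, p = 0.0525) over 500 bp from a start site. The counts of 6-mers fell to 239 more and 218 less frequent against random GC-matched windows. The ratio of ACAGTG to flanks was 2.53 in the main windows and 1.41 in windows of 50 bp. The correlation of CAGGTG with strength passed the threshold with the other series list (rho -0.0420) and in windows of 50 bp (rho -0.0457). The signal correlation was 0.890 within 50 bp and 0.713 over all ranked peaks. With an E-box window of 50 bp and a promoter distance of 1000 bp, the E-box difference between shared and replicate 1 only peaks passed, at -2.48 points (Fisher's exact test, adjusted p = 0.00131) against -2.13 points (adjusted p = 0.0886) in the main comparison, and the promoter difference between the single-replicate sets turned to -2.23 points. Enriched lists numbered 5 in the main list, 1 in the upper part by signal, 1 within 1000 bp of a start site, 3 by gene body and 1 against placements. Apart from GC content, which the matched windows hold equal by construction, the cause was not tested.

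List odds ratios that crossed 1 were temporal factors at 1.08 (other series list), 1.15 to 1.25 (single replicates) and 1.66 (upper part), proneural genes at 0.695 in the main list and 0.261 to 1.80 in single replicates, neuronal genes at 0.939 and ribosomal protein genes at 0.916 (upper part). Within 1000 bp of a start site they were neuroblast 0.923, dorsoventral ectoderm 0.749, imaginal disc 0.554, pair-rule 0.223 and Hox 0.849, and by gene body muscle 0.995 and pair-rule 0.178. Against placements the ratios were neuroblast 0.845, neuronal 0.556, muscle 0.902, dorsoventral ectoderm 0.800, imaginal disc 0.983, adhesion and polarity 0.876 and Hox 0.876. No paired analysis was possible because the series has a single group. Unknown depth limits the reading of weak peaks and of missing ones.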

Other observations

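Tests chosen only after the result was seen are those of GC content, of low-signal peaks, of single libraries and of mitochondrial ribosomal protein genes, and the orientation counts. Genes that share a promoter region with a neighbour on the other strand had peaks more often. Of 5052 genes with an opposite-strand start site within 1000 bp upstream, 29.0% had a summit within 500 bp of a start site, against 8.87% of other genes (odds ratio 4.19, Fisher's exact test, p = 8.38e-203). Such a window can hold the neighbour's peak. A gene counted by any of its annotated start sites, and the number of start sites per gene was not held equal. Counted once per pair, 33.1% of 2667 pairs had a peak, against 17.0% for 2 independent promoters of other genes (exact binomial test, p = 8.55e-91). Some genes were shared between pairs, so the pairs were not all independent as that test assumes.

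Other gene families were also tested, with adjustment over 5 families. Cuticle protein genes had peaks at 7 of 97 members (odds ratio 0.325, Fisher's exact test, adjusted p = 0.00207), though against random placements the ratio was 0.557 (permutation test, adjusted p = 0.150). Homeobox and related patterning genes outside the fixed lists had peaks at 20 of 48 members (odds ratio 2.85, exact test, adjusted p = 0.00207), and 0.829 times the number from placements (permutation test, adjusted p = 0.285). The direction thus turned with the comparison, and the placement value did not pass. Mitochondrial ribosomal protein genes (odds ratio 0.878, 13 of 73) had 2.02 times the placement number (permutation test, adjusted p = 0.0400). Cytochrome P450 genes (odds ratio 0.546) and proteasome genes (odds ratio 0.601) did not pass.

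CAGGTG was less frequent at summits than 1000 bp away. Low-signal peaks beside stronger ones did not pull the share down. CAGGTG was present at 17 of the 148 summits of signal under 20 (11.5%, 6.84 to 17.8), against 5.06% of the others, a difference of 6.43 points (Fisher's exact test, p = 0.00209). The low GC content of summit windows is a candidate explanation and stays a hypothesis. The difference was 0.635 points against GC-matched flanks, a control fixed before the data were examined (exact McNemar test, p = 0.245), and 0.978 points against random GC-matched windows, the value from which the explanation was formed. The flank comparison covered only the summits that had a match. No biological explanation was tested.

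CACTG-containing 6-mers lay on both sides of an AT-rich centre. From 20 to 140 bp from the summit, 73.8% (71.2 to 76.2) of 1228 ACACTG occurrences were on the forward strand to the left of the summit or on the reverse strand to its right (exact binomial test, p = 1.22e-64). The share was 77.8% for CACTGA (exact binomial test, p = 1.01e-79) and 54.9% for CAGGTG (p = 0.0812). CACTGT, the reverse complement of ACAGTG, had the opposite orientation, with a share of 23.5% (21.4 to 25.7, exact binomial test, p = 1.77e-97). The ratio of ACAGTG to GC-matched windows, 2.88, comes from the comparison in which this 6-mer was found. Chosen again on the 1559 peaks of chromosome 2, ACAGTG had a ratio of 3.38 in the 2838 peaks of the other arms (exact McNemar test, p = 6.14e-57), which argues against GC content. Promoter sequence is argued against by a ratio of 2.99 over 500 bp from a start site. Windows that overlapped a transposable element or shared 20 bases with another peak's window numbered 176, against 889 summits with ACAGTG. Such repeats therefore cannot account for most of these summits. The ratio of 3.14 after their removal adds nothing, since so few windows could not bring it under 1.2. It was 3.20 in the replicate with the lower ratio, but the replicates share most sites, so this hardly tested a single library. A sequence preference in the precipitated chromatin is a hypothesis found on the same data. Whether it belongs to Escargot, to another protein in the same chromatin or to a mislabelled sample was not tested.

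Stronger peaks lay at promoters more often, at 60.4% in the strongest of 5 parts and 34.9% in the weakest. If signal followed transcription without specificity, ribosomal protein promoters should carry strong peaks, but the 32 promoter peaks nearest to those genes had a median signal percentile of 25.3 among 1744 peaks within 500 bp of a start site of a protein-coding gene (permutation test, p = 0.00236). For ribosomal protein promoters this argues against signal whose strength follows transcription. Transcription of the genes nearest to the strongest peaks was not measured, so the source of those peaks was not tested. Ribosomal protein genes did have a summit within 1000 bp of a start site more often than other genes (odds ratio 3.31, Fisher's exact test, adjusted p = 6.72e-07) and 2.43 times the placement number of bound members, so signal that follows transcription at weaker peaks stays open. Other gene classes were not tested. No biological explanation was tested.

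In the main list, 148 peaks (3.37%) had a signal value under 20, and each lay 199 to 381 bp from the summit of a stronger peak. Of the main peaks, 802 (18.2%) overlapped no thresholded peak of either single replicate.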
